A study of Mus musculus with 6 samples.

How the data were processed

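The series profiled open chromatin by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA. The cells were OT1 CD8 T cells, which carry a transgenic receptor for an ovalbumin peptide, sorted by CD8 and the congenic marker CD45.1 from B16-OVA-GP61 tumors, a mouse melanoma line that carries ovalbumin and the GP61 epitope. There were 6 libraries in 2 groups of 3: tumors of mice given OT1 cells without SMARTA cells, and tumors of mice given both. SMARTA cells are CD4 T cells whose transgenic receptor recognises GP61. Groups and replicate numbers came from the sample titles. Nothing in the labels says whether replicates came from separate animals, so p-values measure the spread between these libraries, which can include technical spread.

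The deposited count table holds whole-number read counts for 74686 regions in each library, with no normalization. All but 1487 of these regions share a single length, and the longest spans 1474 bases. Each library also has a deposited peak list of its own, called per library and not on pooled reads. Per the file columns, the authors' peak caller gave each peak a score, a fold enrichment (a ratio over local background), a −log10 p, a −log10 q and a summit position, and the score equals the whole part of 10 times the deposited −log10 p. The submitters' processing notes name BWA 0.7.17, SAMtools 1.8, Picard 2.18.9, MACS2 2.1.1 and DiffBind 3.4.11, and the build GRCm38, without their roles or settings. Duplicate removal, the shift of reads for the transposase, the reads counted and the filters behind the region table are not given in the sources used here. Leftover duplicates would inflate counts, and a region table built from peaks of these libraries cannot hold sites open in fewer libraries than its rule asked for. In 74682 of the 74686 regions a peak of 2 or more lists overlaps the region. Peak enrichments and scores are the authors' values and were used here only to describe or rank peaks within a list.

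Total counts in the regions ranged from 16595779 to 27182809 per library, with a median of 62 to 114 counts per region, so most regions have enough counts for replicate spread and not counting error to set the precision. The biological coefficient of variation was 18.0%. Differential accessibility was tested with edgeR 4.0.16 under R 4.3.3 on the counts as deposited: TMM scaling, filterByExpr on the groups (which removed 0 regions), glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment with a threshold of 0.05. The log2 fold is the group with SMARTA cells minus the group without, and its SE is the size of the fold divided by the root of the F statistic. A region past the threshold is called opened where the fold is positive and closed where it is negative. Accessibility per library is given as log2 CPM with a prior count of 2, as mean ± SD over 3 libraries. On counts simulated for the comparison with SMARTA against without, over 74686 regions, the same code recovered 3 of 50 regions changed 1.5-fold, 16 of 50 changed 2-fold, 46 of 50 changed 4-fold and 49 of 50 changed 8-fold. Beside these true calls stood 14 false ones, among 74486 unchanged regions. Far fewer regions were changed than the 11264 called in the real comparison. The adjusted threshold was therefore stricter in the simulation, and its recovery does not carry over directly. A simulated list of 60 regions shifted 1.5-fold was called, and 0 of 20 unchanged lists were. Simulated regions were drawn independently, whereas the estimated correlation was, for example, 0.083 in the exhaustion factor list and 0.27 in the cytotoxic list. The simulated lists therefore do not test the preset correlation on these data.

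No genome sequence was used here, so the planned motif tests and GC corrections were not run. Gene names came from the RefSeq gene table of GRCm38.p6, which gives gene start and end and was used without strand. A region was therefore assigned to the protein-coding gene whose interval holds it, or else to the nearest one within 100 kb, in place of the nearest transcription start site that had been planned. Likewise, distance to either boundary of a gene stands in for distance to a promoter. Exons, introns and UTRs were not distinguished. Of the regions, 46922 lie inside a gene, 24283 were assigned to a neighbour and 3481 have no gene within 100 kb. Assignment does not show which gene a region regulates. Region positions are printed as deposited.

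A total of 21 gene lists with 357 symbols were fixed before the data were examined, 6 of them markers of other cell types. Xcr1 is in 2 lists and no other symbol is in more than 1, and 354 symbols matched the gene table. Activated T cells can express some markers of other cells, among them Itgam, Itgax, Kit and Pecam1. Regions of 331 of these genes were tested. Each list was tested with camera from limma 3.58.1 (preset correlation 0.01) on log2 CPM, with adjustment over the 21 lists. Camera compares the regions of a list with all other regions, also where the list is limited to regions within 2 kb of gene boundaries. Camera with an estimated correlation was run beside it, and fry, which tests whether the regions of a list move in 1 direction on balance or change in either direction, and compares them with no other regions. Genes named in the text follow a rule fixed at the same time. It takes the 10 opened and 10 closed regions with the smallest p among those whose groups do not overlap, up to 4 genes per list by their smallest region p, and Pdcd1, Tox, Havcr2, Entpd1, Tcf7, Slamf6, Ifng, Gzmb, Klrg1, Cd4 and Mlana. Any other gene named was chosen after its values were seen, and is given with its region counts. Some genes that the rule takes are not reported here. Overlaps of peak lists were computed with bedtools 2.31.1 and a minimum of 1 base, and peak numbers were compared by a two-sided exact permutation test.

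Alternatives were RLE, total-count and abundance-trended loess scaling, no low-count filter, DESeq2 1.42.0, the replicate number as a block, leaving out each library in turn, stricter thresholds, other assignments of regions to genes, and other rules for peak lists. Added after the data were seen were counts thinned to the lowest library total, the assignment rules above, gene sets matched on accessibility and number of regions, and the exhaustion factor list with the Tox regions left out.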

Results

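Chromatin accessibility was measured in OT1 CD8 T cells sorted from B16-OVA-GP61 melanomas of mice that had received OT1 cells alone (3 libraries) or together with SMARTA CD4 T cells (3 libraries). The libraries without SMARTA cells held 19149455, 26218921 and 24129749 counts over 74686 regions, and those with SMARTA cells held 20175065, 16595779 and 27182809. Across regions, log2 CPM correlated at r = 0.946 to 0.984 between libraries of a group and at 0.899 to 0.939 between groups, where regions are not independent replicates. The first principal component held 58.3% of the variance and separated the groups. The second component held 19.2% and set replicate 2 with SMARTA cells apart from its group mates, with a score of 89.1 against -72.1 and -36.6. No library pair agreed within sampling noise, the lowest chi-square per degree of freedom being 2.76.

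The comparison asks how the presence of tumor-specific CD4 T cells goes with the chromatin state of tumor-specific CD8 T cells. With SMARTA cells, accessibility fell at regions inside Tox, a transcription factor of T cell exhaustion. Of its 37 tested regions 23 closed and 0 opened, while its most accessible region, near a gene boundary, did not pass. Closed regions also lay at Pdcd1, the gene of the inhibitory receptor PD-1 (6 of 13), and at Ifng, the gene of interferon gamma (10 of 33). The regions assigned to exhaustion transcription factors and to inhibitory receptors passed downward as lists by camera with a preset correlation, and both calls were lost with an estimated correlation (adjusted p = 0.96 each). With an estimated correlation all 21 lists shared that adjusted value. The unadjusted p of camera with an estimated correlation was 0.13 for exhaustion factors and 0.19 for inhibitory receptors, so neither list passed before adjustment. Opened regions were fewer, and several genes held a cluster of them, among them S1pr1, the receptor for T cell egress from tissue (6 of 23 opened, 0 closed), and Lef1, a factor of naive and progenitor T cells (5 of 23 opened, 0 closed), both chosen after their values were seen. Leaving out 1 library lowered these counts to 13 at Tox (without replicate 3 with SMARTA cells), 4 at Pdcd1 and 7 at Ifng (both without replicate 2 of the group without SMARTA cells), 2 at S1pr1 (without replicate 1 of that group) and 3 at Lef1 (without its replicate 2). S1pr1 and Lef1 belong to the naive, memory and progenitor list, which did not pass camera. Its counts went the other way, with 68 closed and 19 opened of 438 regions.

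Of the 74686 regions tested with edgeR, 11264 passed an adjusted p of 0.05, of which 3497 opened and 7767 closed. The median log2 fold was -1.36 among closed regions and 0.77 among opened ones, and 6188 closed and 874 opened regions changed by 2-fold or more. Closed regions were assigned to 3616 genes and opened regions to 2303, with 758 genes holding both. Over all tested regions, the 3 libraries of one group all lay above the 3 of the other in 34.2%, against 10% by chance. The number called fell to 6234 without replicate 2 of the group without SMARTA cells, to 6074 without its replicate 3 and to 6190 without replicate 3 with SMARTA cells. The opened regions fell to 1273, 1224 and 1787 in the same order, and to 1809 without replicate 1 of the group without SMARTA cells. Without replicate 2 with SMARTA cells, 12669 regions passed (4259 opened, 8410 closed).

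Closed regions were mostly of low to intermediate accessibility. Over 5 equal classes of regions by mean log2 CPM, 1605 closed and 159 opened in the lowest class, and 2109 closed and 621 opened in the middle one. In the highest class 480 closed and 1470 opened, but that order turned under abundance-trended loess scaling, with 869 closed and 690 opened. Loess scaling also changed the lowest class, to 971 closed and 690 opened.

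**Figure D1:**
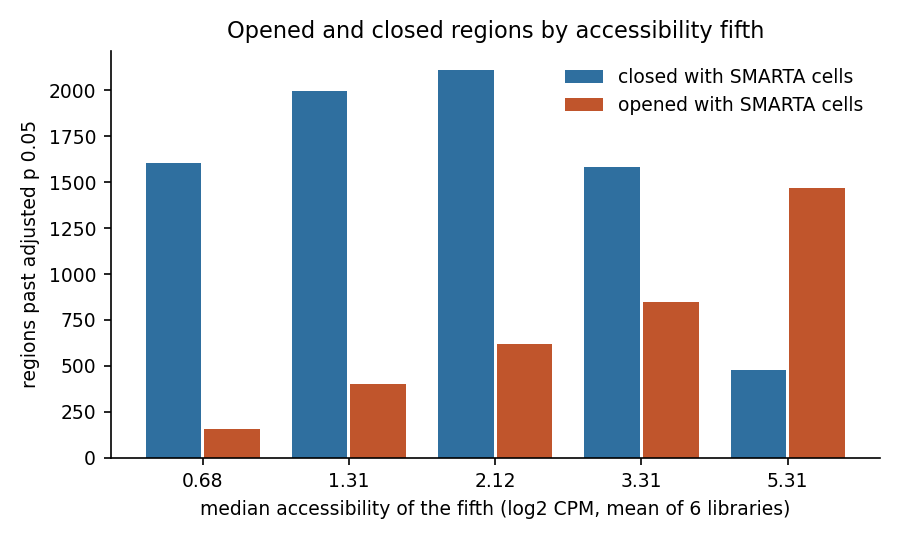
Bars give the number of regions that closed (blue) or opened (orange) with SMARTA cells at an adjusted p under 0.05, for 5 equal classes of the tested regions ordered by mean accessibility, labelled by the median log2 CPM of each class. Closed regions outnumber opened ones in 4 of the 5 classes, and the highest class, with 480 closed and 1470 opened, has the opposite order under loess scaling.

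The closed regions with the smallest p lost nearly all of their signal. A region inside Cep43 (chromosome 17, 8190603 to 8191003, GRCm38) went from 4.39 ± 0.05 to 0.86 ± 0.43 log2 CPM (SD, n = 3 each; log2 fold -3.54 ± 0.23 SE, edgeR adjusted p = 0.00021). Regions near Sucnr1, the succinate receptor (chromosome 3, 60124406 to 60124806, 36.8 kb from the gene; -3.70 ± 0.26), inside Tnr, which encodes tenascin R (-3.66 ± 0.23), and inside Tmem135 (-3.58 ± 0.25) closed by similar amounts. The remaining 6 lay at Scaf4, Uqcrfs1, Abhd4, 2700097O09Rik, Zfp365 and Nfkbiz, with log2 folds from -3.43 at Scaf4 to -2.83 at Nfkbiz. Nfkbiz, which encodes a nuclear regulator of NF-kB, held 13 closed and 0 opened regions among 21 (8 closed without replicate 3 with SMARTA cells).

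Opened regions gained less. The strongest by p lay inside Zscan20 (chromosome 4, 128594060 to 128594460), which rose from 4.20 ± 0.08 to 5.42 ± 0.02 log2 CPM (log2 fold 1.23 ± 0.11, adjusted p = 0.00026). A region inside Tiam1, an exchange factor for the GTPase Rac (chromosome 16, 89986034 to 89986434), rose from 4.39 ± 0.03 to 5.58 ± 0.12 log2 CPM, and 6 of the 27 Tiam1 regions opened (3 without replicate 3 with SMARTA cells). Larger gains were at St8sia1, a ganglioside sialyltransferase (chromosome 6, 142954841 to 142955241; 2.27 ± 0.24, 11 of 35 regions opened, and 5 without replicate 2 of the group without SMARTA cells), and near Cpn2 (2.05 ± 0.22). Regions at Rnf125, Ldlrad4, Als2cl, Elovl5 and Spef2 opened by 0.92 to 1.46.

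Exhaustion transcription factors had the lowest adjusted p of the 21 lists. Of their 285 regions, 81 closed, 13 opened and the rest did not pass, and of the 16 genes 7 held closed regions without opened ones, 9 held both and 0 held opened regions alone. With adjustment over the list alone, 98 regions closed and 22 opened. The list's median log2 fold was -0.32 (camera adjusted p = 3.4e-05), a call lost with an estimated correlation (adjusted p = 0.96 with an estimated correlation). The strongest region of a gene is here the one with the smallest p. For Tox it (chromosome 4, 6834301 to 6834701, inside the gene) fell from 2.77 ± 0.26 to -0.22 ± 0.24 log2 CPM, a log2 fold of -3.13 ± 0.25 (adjusted p = 0.00021). All 23 closed Tox regions lay inside the gene between 6748245 and 6958496, with log2 folds from -3.43 to -0.57. The most accessible Tox region, 0.15 kb from a gene boundary, did not pass (5.07 ± 0.07 to 4.89 ± 0.10 log2 CPM, edgeR adjusted p = 0.29). Regions 1.69 and 2.27 kb from a boundary did not pass either (edgeR adjusted p = 0.33 and 0.14). Prdm1, which encodes Blimp-1, held 8 closed and 1 opened of 28 regions, Ikzf2, which encodes Helios, 7 closed and 2 opened of 22, and Nfatc1, a calcium-regulated factor downstream of the T cell receptor, 12 closed and 1 opened of 37. Their strongest regions closed by -2.24 ± 0.22, -2.61 ± 0.25 and -1.60 ± 0.19. Tox2, chosen after its values were seen, held 5 closed and 0 opened of 9. Without replicate 2 of the group without SMARTA cells, 5 Nfatc1 and 2 Tox2 regions closed, and without replicate 1 of that group 4 Prdm1 regions. With the Tox regions left out the list held 58 closed of 248 (camera adjusted p = 0.0018). Restricted to regions within 2 kb of a gene boundary it did not pass (camera adjusted p = 0.43). That setting compares boundary regions with all others, so it cannot separate the list from its position. The list's counts fell to 43 closed and 6 opened without replicate 3 with SMARTA cells, and to 51 closed with 3 or 1 opened without replicate 2 or 3 of the other group. Without replicate 2 with SMARTA cells, 82 closed and 16 opened. The opened regions at Prdm1, Ikzf2 and Nfatc1 fell to 0 each without replicates 3, 1 and 2 of the group without SMARTA cells in that order.

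**Figure D2:**
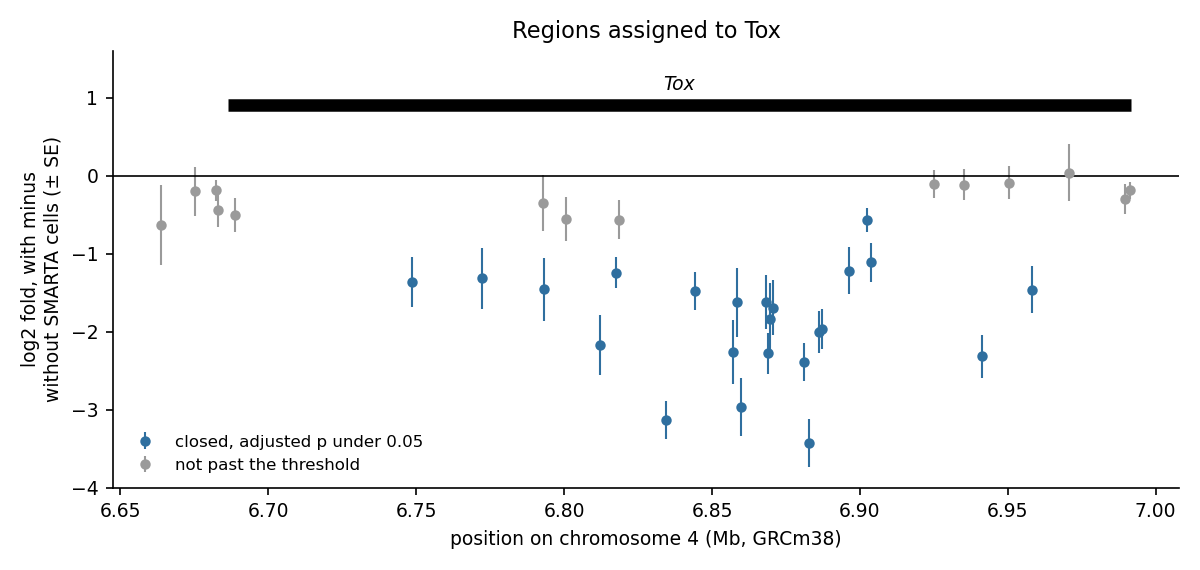
Each point is 1 of the 37 regions assigned to Tox, placed by its position on chromosome 4 (Mb, GRCm38) and its log2 fold with SMARTA cells minus without, with bars of 1 SE; the black bar is the Tox gene interval. The 23 closed regions (blue) range from -3.43 to -0.57 and all lie inside the gene.

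Regions of inhibitory receptors also passed camera downward. Of 150 regions, 32 closed and 4 opened, and of 15 genes 9 held closed regions without opened ones, 1 held opened regions alone, 3 held both and 2 had neither. Adjusted over the list alone, 35 closed and 7 opened. The median log2 fold was -0.31 (camera adjusted p = 0.00013; adjusted p = 0.96 with an estimated correlation). At Lag3, 4 of 7 regions closed, the strongest by -1.37 ± 0.13 (chromosome 6, 124911545 to 124911945). At Tigit, 4 of 11 regions closed, the strongest by -3.20 ± 0.31 (chromosome 16, 43628664 to 43629064). Cd200, the ligand of an inhibitory receptor, held 4 closed of 7 regions, and its receptor gene Cd200r1 held 1 of 5, by -2.96 ± 0.27. The strongest Pdcd1 region, inside the gene (chromosome 1, 94042163 to 94042563), fell from 4.98 ± 0.15 to 3.98 ± 0.23 log2 CPM (-0.99 ± 0.15, adjusted p = 0.0025), and 1 Pdcd1 region opened (0 without replicate 3 of the group without SMARTA cells). Without replicate 3 of the group without SMARTA cells, 21 regions of the list closed and 0 opened, among them 2 closed each at Tigit and Cd200. Without replicate 2 of that group 23 closed and 1 opened, without replicate 3 with SMARTA cells 22 and 1, and without replicate 2 with them 35 and 8. Entpd1, which encodes CD39, held 2 closed of 17 regions, the strongest by -2.42 ± 0.34. None of the 7 regions of Havcr2, which encodes TIM-3, passed, and the one with the smallest p had a log2 fold of -0.51 ± 0.19 (edgeR adjusted p = 0.094).

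**Figure D3:**
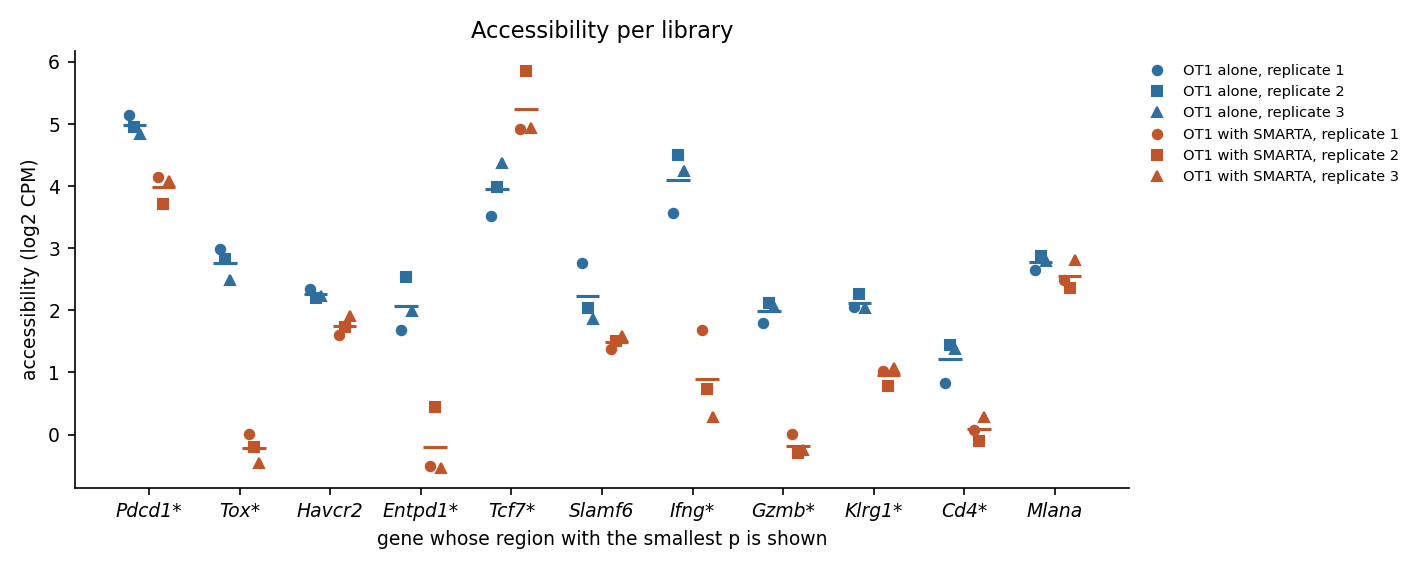
Points give log2 CPM per library for the region with the smallest p at each of 11 genes fixed in advance, blue for OT1 cells alone and orange for OT1 cells with SMARTA cells, with a marker shape for each replicate, lines at the group means (n = 3 each) and an asterisk where the region passed an adjusted p of 0.05. Among the genes with an asterisk, Tcf7 rose, by 1.30, and the others fell.

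Cytotoxic and effector molecules had 36 closed and 3 opened of 169 regions (38 and 3 adjusted over the list alone; median log2 fold -0.21, camera adjusted p = 0.0013; adjusted p = 0.96 with an estimated correlation). Of 20 genes, 9 held closed regions alone, 1 opened regions alone, 2 both and 8 neither. A region 54.0 kb from Ifng (chromosome 10, 118386673 to 118387073) fell from 4.10 ± 0.49 to 0.89 ± 0.71 log2 CPM (-3.22 ± 0.38, adjusted p = 0.00061). Gzmb, which encodes granzyme B, held 4 closed of 13 regions, the strongest 29.0 kb away (-2.29 ± 0.23), and Fasl, the death ligand, 5 closed of 21 (-1.81 ± 0.27), counts that fell to 1 and 3 without replicate 2 of the group without SMARTA cells. Genes of effector differentiation had 36 closed and 3 opened of 245 regions (39 and 3 adjusted over the list alone; median -0.20, adjusted p = 0.0013; adjusted p = 0.96 with an estimated correlation), with 9 of 16 genes holding closed regions alone, 3 both and 4 neither. There, Cx3cr1, a chemokine receptor of effector cells, had 4 closed and 1 opened of 10 regions (-2.62 ± 0.27 at the strongest; 0 opened without replicate 2 of the group without SMARTA cells), Il12rb2, an interleukin-12 receptor chain, 5 closed and 1 opened of 22 (-2.61 ± 0.26), and regions at Klrc1, which encodes NKG2A, and at Klrg1 closed by -3.28 ± 0.33 and -1.19 ± 0.20. The cytotoxic list fell to 16 closed without replicate 3 with SMARTA cells, and to 17 and 19 without replicates 3 and 2 of the other group. The effector differentiation list fell to 22 in the first 2 of these settings and to 21 in the third. The opened regions of both lists rose from 3 to 8 without replicate 2 with SMARTA cells, and fell to 1 without replicate 2 of the other group.

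Costimulatory receptors and ligands had 42 closed and 11 opened of 196 regions (48 and 13 adjusted over the list alone; median -0.16, camera adjusted p = 0.010; adjusted p = 0.96 with an estimated correlation). Of the 16 genes, 10 held closed regions alone, 5 both and 1 neither. Tnfsf8, the CD30 ligand, held 9 closed of 15 regions (-2.33 ± 0.24 at the strongest), Tnfsf4, the OX40 ligand, 4 of 9 (-2.27 ± 0.26) and Tnfrsf9, an inducible receptor of activated T cells, 5 of 12 (-1.85 ± 0.22). Without replicate 2 of the group without SMARTA cells 5 Tnfsf8 regions closed, and without replicate 1 of that group 2 Tnfrsf9 regions. Icos held 3 opened and 2 closed of 25 regions, with its strongest region closed (-2.03 ± 0.25), and the opened ones fell to 0 without replicate 3 of the group without SMARTA cells and to 1 under another scaling. The closed regions of the list fell to 24 and 27 without replicates 2 and 3 of the group without SMARTA cells and to 25 without replicate 3 with them, and the opened ones to 4, 3 and 3. The opened ones also fell to 5 under total-count scaling and 7 with the replicate block, where 45 and 41 closed, and to 5 without replicate 1 of the group without SMARTA cells. Without replicate 2 with SMARTA cells, the library set apart on the second component, the calls of the cytotoxic (adjusted p = 0.14), effector differentiation (0.10) and costimulatory (0.14) lists were lost, while exhaustion factors (0.0019) and inhibitory receptors (0.0061) still passed. These were the highest values of each list when 1 library was left out, and the lowest were 1.1e-06, 1.6e-05, 0.00081, 8.9e-07 and 9.1e-06 in the same order. The cytotoxic list also did not pass with regions within 2 kb of a gene boundary (0.43) or from 20 kb before to 20 kb after the gene (0.18). No list passed fry in 1 direction (lowest adjusted p = 0.15), and all 21 passed fry in either direction. Fry does not compare a list with other regions.

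**Figure D4:**
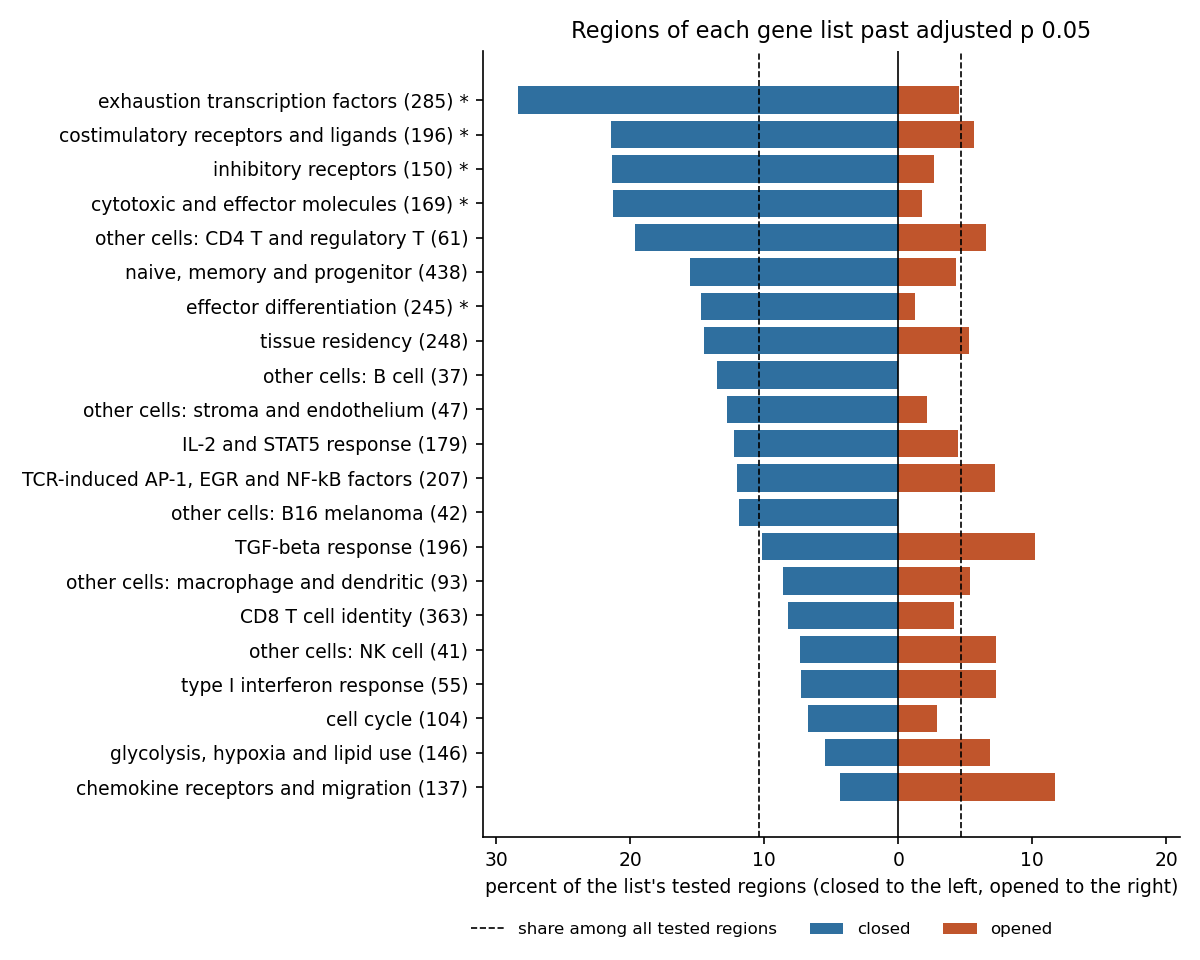
Bars give, for each of the 21 gene lists with its number of tested regions in brackets, the percent of regions that closed (blue, to the left) or opened (orange, to the right), and dashed lines the shares among all tested regions, 10.4% and 4.68%. The 5 lists with an asterisk passed camera's adjusted p of 0.05 with a preset correlation and none passed with an estimated one, and exhaustion transcription factors had the highest closed share, 28.4%.

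Naive, memory and progenitor genes did not pass camera as a list (68 closed and 19 opened of 438 regions; median -0.04, camera adjusted p = 0.42), and its members went apart. Bach2, a repressor of effector programs, held 13 closed and 0 opened of 56 regions (-2.56 ± 0.31 at the strongest), Bcl2, a survival factor, 8 closed of 34 (-2.55 ± 0.22), Ccr7, the lymph node homing receptor, 4 closed of 15 (-3.41 ± 0.31), and Foxp1 13 closed and 5 opened of 82 (2 opened without replicate 1 of the group without SMARTA cells and up to 10 without another library). Without replicate 3 of the group without SMARTA cells, 4 Bcl2 and 8 Foxp1 regions closed, and the list fell to 42 closed and 10 opened (66 and 29 without replicate 2 with SMARTA cells). Tcf7, which encodes TCF1, a factor of progenitor cells, held 1 opened and 0 closed of 17 regions: a region inside the gene (chromosome 11, 52275391 to 52275791) went from 3.96 ± 0.43 to 5.24 ± 0.54 log2 CPM (1.30 ± 0.28, adjusted p = 0.011). The strongest of 9 Slamf6 regions had a log2 fold of -0.79 ± 0.26 and did not pass (edgeR adjusted p = 0.065). Chosen after its values were seen, Myb, a factor of progenitor cells, held 11 closed and 0 opened of 20 regions, and 3 Myb regions closed without replicate 3 with SMARTA cells.

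Chemokine receptors and migration genes had more opened than closed regions, 16 against 6 of 137 (18 and 7 adjusted over the list alone), with a median of 0.10 that did not pass (camera adjusted p = 0.076). The list passed upward without replicate 2 with SMARTA cells (0.0061; the highest when 1 library was left out was 0.23), without replicate 2 of the other group (0.049), under loess scaling (0.042), and with the regions within 2 kb of a gene boundary (0.021) or from 20 kb before to 20 kb after the gene (0.0095). The pass within 2 kb of boundaries cannot be told from position, since camera compared those regions with all others. The list did not pass with an estimated correlation (0.96) or by fry in 1 direction (0.32). It had 5 opened and 3 closed regions without replicate 3 with SMARTA cells, and 8 and 6, 8 and 3, and 6 and 5 without replicates 1, 2 and 3 of the other group. Cxcr3, a receptor of effector T cells, held 2 opened and 1 closed of 9 regions (1 opened without replicate 1 of the group without SMARTA cells), with the strongest opened by 0.95 ± 0.18, and an Itgb7 region opened by 0.67 ± 0.10. Cxcr4 held 3 opened regions (1 without replicate 3 of that group), and its strongest region closed (-1.83 ± 0.20). Ccr8 held 1 opened and 1 closed of 5 regions, the closed one 0.69 kb from the gene (-1.01 ± 0.16).

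The other 8 lists of T cell programs did not pass. TGF-beta response genes had 20 opened and 20 closed of 196 regions (adjusted p = 0.47), with closed regions at Tgif1 (5 of 15) and, chosen after their values were seen, opened regions at Ski (5 of 14) and Pmepa1 (5 of 13), where 1 region each opened without replicate 2 of the group without SMARTA cells. The closed regions at Tgif1 fell to 2 without that library. TCR-induced factors had 15 opened and 25 closed of 207 (0.89), with 5 of 7 regions closed at Rel (2 without replicate 3 of the group without SMARTA cells) and 6 of 35 at Nfkb1 (3 without its replicate 2). Tissue residency genes had 13 opened and 36 closed of 248 (0.42), 23 of the latter at Inpp4b, and a Qpct region opened by 1.67 ± 0.22. The IL-2 and STAT5 response had 8 opened and 22 closed of 179 (0.70), with 5 closed at Tnfrsf8, which encodes CD30 (3 without replicate 2 of the group without SMARTA cells). Glycolysis, hypoxia and lipid use had 10 opened and 8 closed of 146 (0.47), with 4 of 18 closed at Hif1a and a region opened at Slc2a1, a glucose transporter (0.53 ± 0.09). The cell cycle list had 3 opened and 7 closed of 104 (0.93), with 4 of 13 closed at Ccne1 and regions opened at Cdk6 (1.22 ± 0.18) and E2f2 (0.89 ± 0.14). Type I interferon response genes had 4 opened and 4 closed of 55 (0.25), where 2 of 7 closed at Ifih1, which encodes a sensor of viral RNA, and 1 each opened at Oas3 and Bst2, calls lost when 1 library was left out (adjusted p up to 0.098 and 0.096). CD8 T cell identity had 15 opened and 30 closed of 363 (0.89), with 2 closed at Zap70 and with 6 opened and 7 closed at Runx1 (3 closed without replicate 2 and 2 opened without replicate 3 of the group without SMARTA cells). When 1 library was left out, the opened regions ran from 7 to 27 in the TGF-beta, 4 to 19 in the TCR-induced, 6 to 24 in the tissue residency, 2 to 15 in the IL-2, 4 to 13 in the glycolysis, 2 to 6 in the cell cycle, 0 to 5 in the interferon and 4 to 24 in the identity list. The closed ones ran from 12 to 22, 12 to 28, 25 to 43, 9 to 20, 6 to 9, 3 to 6, 2 to 4 and 13 to 33 in the same order. In the TGF-beta, TCR-induced, IL-2, glycolysis and identity lists the median lay above 0 and the mean below it, and under total-count scaling the medians of the TCR-induced, glycolysis and identity lists also lay below 0. With only regions within 2 kb of a gene boundary, the TCR-induced, interferon and TGF-beta lists (each camera adjusted p = 0.0081) and the tissue residency list (0.021) passed upward. Camera compared these boundary regions with all other regions, most of them away from boundaries, where closed regions were more frequent. These passes therefore cannot be told from a difference between boundary regions and the rest.

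No list of markers of other cells passed camera. The lists of CD4 and regulatory T cells (12 closed and 4 opened of 61; adjusted p = 0.25), B16 melanoma (5 and 0 of 42; 0.59), macrophages and dendritic cells (8 and 5 of 93; 0.93), B cells (5 and 0 of 37; 0.14), NK cells (3 and 3 of 41; 0.92) and stroma and endothelium (6 and 1 of 47; 0.42) all had closed regions. When 1 library was left out, the closed counts ran from 5 to 15, 1 to 4, 7 to 9, 2 to 5, 2 to 3 and 3 to 6 in the same order, and the opened ones from 1 to 5, 0 to 1, 1 to 7, 0 to 0, 0 to 1 and 1 to 2. The median of the macrophage list lay above 0 and its mean below it, and the test and median of the NK list differed in sign. Cd4 held 1 closed of 3 regions (-1.21 ± 0.28, adjusted p = 0.016), a call lost without replicate 2 or replicate 3 of the group without SMARTA cells (0.073 and 0.074). None of the 2 Mlana regions passed (-0.21 ± 0.20 at the smaller p, edgeR adjusted p = 0.53). Named regions closed at Lrrc32 (-2.48 ± 0.26), a molecule of activated regulatory T cells, at Itgam (-2.28 ± 0.28), an integrin of myeloid cells, at Pecam1 (-1.70 ± 0.18), which T cells can also express, and at Kit (-1.80 ± 0.36). Regions opened at Il5 (1.08 ± 0.18) and at Vwf, an endothelial gene (1.21 ± 0.20).

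Closed regions lay away from gene boundaries, in a comparison not matched on accessibility, with which the number of closed regions also varied. Of the 7767 closed regions, 746 (9.60%) lay within 2 kb of a boundary of a protein-coding gene, against 24.6% of all tested regions (odds ratio 0.30, 95% interval 0.27 to 0.32, Fisher's exact test, which treats regions as independent). Of the opened regions 933 (26.7%) did so (odds ratio 1.12, 1.04 to 1.21), and that direction turned under total-count scaling (19.0%) and loess scaling (11.2%), and without any 1 of the 3 libraries of the group without SMARTA cells (16.6% to 24.2%) or replicate 2 with them (18.2%).

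The peak lists, called per library from the same sequenced libraries, were compared by overlap. They held 73012, 82089 and 81223 peaks without SMARTA cells and 76850, 65020 and 75261 with them, a difference of means of -6398 that did not pass (two-sided exact permutation p = 0.3, where 0.1 is the smallest that 3 against 3 allows). Of the regions in the count table, 2680 overlapped a peak in all 3 lists without SMARTA cells and in none with them, and 594 the reverse. At equal list lengths these counts were 2339 and 974. The first count rose to 5126 without replicate 1 of the group without SMARTA cells and to 4330 without replicate 1 with them. The reverse count rose to 1781 without replicate 2 with SMARTA cells, to 939 without its group mate replicate 1, and to 1029 and 1011 without replicates 2 and 3 of the other group. Of the regions that closed by edgeR, 38.9% had no peak in any list with SMARTA cells and 85.6% had one in all 3 lists without. Of the opened regions, 9.84% had no peak in any list without SMARTA cells, and 79.3% had one in all 3 of those lists. Among regions not called, 73.2% had a peak in all 3 lists without SMARTA cells. No list without SMARTA cells held a peak for 3.12% of them, and no list with SMARTA cells for 4.91%.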

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

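Of the tests in this part, those on library scaling and on loss of other cells were chosen only after the result was seen, as were the thinned counts and the matched gene sets.

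The peak lists hold signal outside the regions of the count table. After merging, 38 peaks outside it were in all 3 lists with SMARTA cells and in no list without, against 57 in the opposite arrangement. Of 105726 merged peaks, 28746 lay outside the table, of which 24884 were in 1 list and 1142 in all 6.

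More regions closed (7767) than opened (3497) with SMARTA cells. Scaling as the whole cause is argued against by the closed share, which stayed at 67.2% or more under RLE, total-count and loess scaling. Unequal depth is argued against by thinned counts, where 69.6% of called regions closed. The 10 splits of the 6 libraries are too few for a share under 0.05: 1 split, the real one, gave as many regions (11264), and the highest of the others gave 0 by edgeR, with up to 2798 at an unadjusted p under 0.05. Each of the others set libraries of both groups on each side, so a group difference adds to their replicate spread. Their low counts therefore do not measure what chance gives. Whether the transferred cells changed state or other OT1 cells were present in the tumors was not tested.

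Of the regions of inhibitory receptors 32 of 150 closed and 4 opened, and of exhaustion factors 81 of 285 and 13. The camera calls of both lists were lost with an estimated correlation (adjusted p = 0.96 each, as for all 21 lists). Accessibility and the number of regions per gene are argued against as the cause, since the median of both lists together (-0.31) lay at the 0.01 percentile of 10000 matched gene sets, the smallest they can give. Loss of macrophages or dendritic cells is argued against by the list of their markers, whose median lay 0.36 above (95% gene bootstrap 0.11 to 0.51), although 8 of its regions closed against 5 opened and an Itgam region closed by -2.28 (levels in log2 CPM without and with SMARTA cells: Cebpb 5.51 and 5.76, Itgam 5.12 and 5.34, Zbtb46 4.74 and 4.73, none past the threshold). Cebpb and Zbtb46 are outside the naming rule. Cebpb held 3 opened and 2 closed of 15 regions, and Zbtb46 held 0 called of 8. Loss of B16 cells cannot be told apart on these regions, since the melanoma list lay 0.12 above with an interval of -0.23 to 0.52. Of its regions 5 closed, 3 at Kit and 1 each at Met and Trpm1, and 0 opened. No region was assigned to its members Tyr, Tyrp1, Oca2, Slc45a2 and S100b, so the list does not cover them. Levels without and with SMARTA cells were 5.55 and 5.79 log2 CPM at Pmel (0 of 2 regions called) and 4.88 and 5.21 at Mitf. Neither passed the threshold, while Kit went from 4.48 to 2.53 (edgeR adjusted p = 0.0084). The sort on CD8 and CD45.1 would, however, remove B16 cells as well as macrophages and dendritic cells. Whether each cell changed or the share of exhausted OT1 cells fell stays open, since bulk counts average over cells.

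Replicate 2 with SMARTA cells stood apart from its group mates. Lower depth is argued against, since after thinning to 1 total the correlation gap kept 92.8% of its size. An admixture of cells from tumors without SMARTA cells is argued against by its shift in the called direction at regions called without it, 1.12 on the log2 scale, against 1.01 and 1.36 for its mates, and by the highest score of the 6 on the first component (106). What sets the library apart stays open.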

How the results depend on the processing

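The thinned counts, matched gene sets, rules of assignment to genes and the list without Tox regions were chosen after the data were seen. Motif tests and GC corrections, alone or with the block, were not run. The low-count filter removed 0 regions, so leaving it out says nothing. The cause of a change below was not tested unless given. Regions past the threshold numbered 11285 with RLE, 10812 with total counts, 11225 with loess, 11787 with DESeq2 and 10415 with thinned counts, of which 11159, 10338, 9529, 10293 and 9911 were among the 11264. At an adjusted p under 0.01, 4491 passed (732 opened, 3759 closed), and with a fold of at least 2, 7062 did (874 opened, 6188 closed), by construction fewer. Without 1 library the total ran from 6074 to 12669, opened from 1224 to 4259 and closed from 4403 to 8410. With the replicate number as a replicate block, 10475 passed; same-numbered libraries did not deviate together (r = -0.02, -0.08 and 0.08), and 1 of 3 correlated best with its own number. The simulated test recovered 3 of 50 regions changed 1.5-fold.

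Of 21 lists, 5 passed; 0 did with an estimated correlation or by fry in 1 direction, 8 within 2 kb of gene boundaries, and 3 to 6 without 1 library. List medians that changed sign were, under total counts, TCR-induced factors -0.0093, glycolysis -0.015 and CD8 identity -0.021; under loess, stroma 0.033; with the block, CD8 identity -0.0014; within 2 kb of boundaries, naive 0.035, tissue residency 0.20 and cell cycle 0.058; and from 20 kb before to 20 kb after the gene, cell cycle 0.025, CD4 and regulatory T 0.013, B16 0.080 and NK 0.070. Without 1 library the medians ran from -0.11 to 0.040 for naive, -0.16 to 0.0018 for tissue residency, -0.016 to 0.046 for TCR-induced, -0.054 to 0.0054 for cell cycle, -0.015 to 0.069 for CD8 identity, -0.28 to 0.037 for B16, -0.056 to 0.073 for macrophage and -0.060 to 0.12 for NK lists. Of these lists, only tissue residency and TCR-induced factors passed in any of these settings, both within 2 kb of boundaries. There, camera compared boundary regions with all others, which cannot separate a list from its position.

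The share of opened regions near gene boundaries was 19.0% with total counts and 11.2% with loess, below that of all regions, and 16.6% to 34.1% without 1 library. Regions with peaks in all 3 lists of one group and none of the other numbered 2819 to 5126 (without SMARTA cells) and 749 to 1781 (with them) when 1 list was left out, where fewer lists make the rule easier to meet, and 974 for the second at equal list lengths. Of 106 named regions past the threshold, 84 passed under every setting, 22 lost the call under at least 1, stricter thresholds included, and 0 changed sign. Of 5 that had not passed, 2 did under another setting.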

Other observations

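The genes counted here, the clustering test, the restrainer genes and the matched gene sets were chosen only after the calls were seen.

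Beyond the fixed lists, the genes with the most closed regions were Ubash3b, a phosphatase that restrains T cell receptor signalling (26 of 48 closed, 0 opened; 18 to 27 closed when 1 library was left out), Acoxl (21 of 33), Hivep3 (19 of 47), F13a1 (16 of 39), Prkca (15 of 42), Rgs8 (14 of 23), St6galnac3 (14 of 21) and Runx2, a transcription factor related to Runx1 and Runx3 (14 of 61). Among other genes, Irf8, an interferon regulatory factor, held 12 closed and 0 opened of 22, Nrp1, which encodes neuropilin-1, 12 closed and 1 opened of 65, and Cblb, a ubiquitin ligase that limits T cell activation, 12 closed of 48, which fell to 2 without replicate 2 of the group without SMARTA cells. Leaving out replicate 3 with SMARTA cells lowered Acoxl to 11, Hivep3 to 11 and Rgs8 to 8.

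The genes with the most opened regions were Gramd3 (13 of 34), Thada (12 of 36), St8sia1 (11 of 35), Slco3a1 (9 of 30) and Znrf1 (9 of 17), and among other genes Arl4c (7 of 27), the integrin chain Itgb3 (7 of 17) and Trat1, an adaptor that associates with the T cell receptor (7 of 14, median log2 fold 1.04). Closed regions numbered 4 at Thada, 2 at St8sia1, 1 each at Gramd3, Slco3a1 and Arl4c, and 0 at Znrf1, Itgb3 and Trat1. Without replicate 2 of the group without SMARTA cells the opened regions fell to 2 at Gramd3, 6 at Thada, 5 each at St8sia1, Slco3a1 and Znrf1, 4 at Trat1 and 1 at Itgb3, and under another scaling they fell to 4 at Itgb3.

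Called regions gathered in the same genes more than in shuffles matched on accessibility, which did not hold distance to a gene boundary fixed. Closed regions were rarer within 2 kb of boundaries (9.60% against 24.6% of all tested), so position could add to their excess. There were 258 genes with 5 or more closed regions, against 98.3 on average and at most 122 in 1000 shuffles of the call among regions of like accessibility. For opened regions there were 49 such genes, against 6.82 on average and at most 15. This is consistent with changes shared along a locus, as a hypothesis, and does not show which gene such a locus regulates.

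A hypothesis drawn from Ubash3b and Cblb was that restrainers of T cell receptor signalling lose accessibility as a group. Among 20 other restrainers, 25 of 199 regions closed and 10 opened. Both counts lay near the shares over all tested regions, 10.4% closed and 4.68% opened. The median log2 fold of these restrainers lay at the 7.39 percentile of 10000 matched gene sets, which leaves the hypothesis open. Spry2 held 6 closed of 9 regions, and Sla and Rasa2 held 4 each, of 19 and 17, while 4 of 13 Ptpn2 regions opened.

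Among all 21 fixed lists set against matched gene sets, 4 had a median that few sets reached, after adjustment over the lists. These were inhibitory receptors (adjusted p = 0.0042, at the smallest percentile the sets can give), exhaustion factors (0.0063), cytotoxic molecules (0.027) and effector differentiation (0.040). The costimulatory list did not pass this test (0.16). Random gene sets treat genes as independent and leave out the spread between libraries. None of the 4 lists passed camera with an estimated correlation (adjusted p = 0.96 each, as for all 21 lists) or fry in 1 direction (lowest adjusted p = 0.15). Without replicate 2 with SMARTA cells, the cytotoxic and effector differentiation lists also did not pass camera (0.14 and 0.10).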
